A study of Mus musculus with 2 samples.

How the data were processed

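Droplet-based single-cell RNA sequencing was applied to dissociated mouse lung in 2 libraries of 1 group, each taken on day 6 after BHT. BHT in lung injury models usually stands for butylated hydroxytoluene, an antioxidant that damages the alveolar lining of mice. The mice carried a tamoxifen-inducible Cre under the Sftpc promoter, a Cre-dependent tdTomato reporter and a Ctgf-GFP reporter, and received tamoxifen first. Per the labels' protocols, cells carrying CD45 (leukocytes) or CD31 (endothelium) were depleted on magnetic columns before capture with the 10x Genomics 3′ v3.1 chemistry. The labels number the libraries as repeats and do not state whether they came from separate animals. All p-values therefore rest only on how far the differences between clusters vary between these 2 libraries, and that variation may be technical. There were no untreated samples, so no comparison between treatment groups was made.

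The authors deposited UMI counts per matrix row and barcode, made with Cell Ranger 7.0.1 per the file headers. The genome builds mm10 and GRCm38.p4 come from the submitters' processing notes. The gene annotation and the treatment of intronic reads are not given in the sources used here. No barcode in either deposited matrix held fewer than 500 UMIs, so a lower limit on UMIs had been applied before deposit. Each matrix has 32285 rows. A table pairing rows with genes was not used here, and gene names were not inferred from the order of the rows. Rows are therefore referred to by their number, clusters are not given cell type names, and no genomic coordinates are given. The planned comparisons of named cell classes, the marker and pathway lists and the tdTomato and GFP reporters need gene names and were not analysed here. No filter on mitochondrial content was possible for the same reason.

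Barcodes with at least 500 detected rows were kept, and Scrublet (scanpy 1.11.5) was run on each library. It called 262 of 10028 barcodes in library 1 (2.61%) as doublets and 1 of 5121 in library 2 (0.0195%), so doublet removal did not work in library 2. Counts were scaled to 10000 UMIs per barcode and transformed as log(1 + x). The 2000 most variable rows over both libraries, 30 principal components, 15 neighbours and the Leiden algorithm at resolution 0.5 (igraph 0.11.9) gave the clusters, with no batch integration. Clusters were numbered by size. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. The libraries were compared on log2(CPM + 1) of summed counts over rows with at least 100 UMIs in both together. With 1 library on each side that comparison has no replicate check and no p-value.

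Differences between clusters were tested on UMI counts summed per library and cluster with edgeR 4.0.16 under R 4.3.3 (TMM, filterByExpr, quasi-likelihood F test). All clusters with at least 20 barcodes in both libraries entered 1 fit with the library as a block, and each cluster was set against the mean of the others. The 13 residual degrees of freedom come from 14 clusters in 2 libraries, not from 13 further samples. Rows were called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change over 1. Because clusters were found from the same counts, these p-values are too small for the rows that define a cluster. An alternative therefore split the UMIs at random into 2 equal parts, clustered on 1 part and tested the other. The fit was also run on simulated data made for cluster 3 against the others over 14269 rows. It recovered 50 of 50 rows at a true fold of 4 and 50 of 50 at 0.25. At folds of 8 and 0.125 it recovered 50 of 50 and 49 of 50, with 4 false calls. Only these rows, all well covered, were changed there, in 1 given cluster and at 1 fixed dispersion. The simulation therefore gives no error rate for the real data, where clusters came from the counts and far more rows were called. The rule for single rows allowed at most 2 that rose and 2 that fell, those of largest fold change in the cluster with the most calls.

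The design, the row rule and most alternatives were fixed before the data were examined. The alternatives were barcode filters of 200 and 1000 detected rows, doublets kept, Leiden resolutions 0.25 and 1.0, 4000 variable rows, centring of each row within each library, DESeq2 1.42.0, no filter on low counts, no library block, other scalings and pseudocounts, and each library alone. A further 4 were chosen after seeing the data, namely the doublet score threshold of library 1 applied to both libraries, clustering of barcodes thinned to 1000 UMIs, omission of shallow clusters, and equal cluster weights in both libraries.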

Results

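Single-cell transcriptomes were collected from lungs enriched for epithelial and mesenchymal cells 6 days after BHT. Library 1 held 11642 barcodes and 79296761 UMIs, and library 2 held 6242 barcodes and 61719663 UMIs. UMIs were found on 25880 matrix rows in library 1 and on 25214 in library 2. After removal of barcodes with under 500 detected rows and of predicted doublets, 9766 barcodes remained in library 1 and 5120 in library 2. The retained barcodes of library 1 had a median of 4923 UMIs (quartiles 2258 and 9441) and 2180 detected rows. Those of library 2 were deeper, with a median of 7172 UMIs (quartiles 2399 and 15609) and 2826 detected rows. Over the libraries the median was 6048 ± 1590 UMIs and 2503 ± 457 detected rows (SD, n = 2). A single row took 4.86% of all UMIs in library 1 and 3.75% of those in library 2.

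The first question was how far the 2 repeats of the injury gave the same transcriptome. Summed over all retained barcodes, the libraries were close: across 16377 rows, log2(CPM + 1) correlated with Pearson's r = 0.994 and Spearman's rho = 0.994. These coefficients are across rows, which are not independent replicates. Only 58 rows (0.354%) differed by more than 2-fold, 49 of them higher in library 1 and 9 higher in library 2. Between 2 random equal parts of the UMIs of 1 library, 0 rows differed by more than 2-fold in either library. The 58 rows thus exceed the counting error of UMIs. Both parts hold the same barcodes, so the split leaves out the sampling of different barcodes. Between the libraries, 128 rows differed by more than 2-fold with a pseudocount of 0.1 CPM instead of 1 CPM. With barcodes thinned to 1000 UMIs, 84 of 10949 rows (0.767%) did. When every cluster was given the same weight in both libraries, an alternative chosen after seeing the data, 32 rows differed by more than 2-fold, and 28 of these were among the 58. With a single library on each side, these differences have no replicate check.

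The cells fell into 15 clusters, and each of the 15 held barcodes of both libraries. At the higher Leiden resolution of 1.0 there were 24. Cluster 1 was the largest, with 17.7% of the retained barcodes of library 1 and 22.3% of those of library 2. The mean shares of clusters 2, 4 and 3 were 16.2% ± 3.78 (SD, n = 2), 12.4% ± 4.74 and 10.8% ± 3.57. The order of sizes differed between the libraries and between settings. With at least 1000 detected rows, cluster 4 fell to 3.26% and cluster 1 (13.9%) was below cluster 2 (14.8%), and at resolution 1.0 the closest matches of clusters 1 and 2 held 9.05% and 3.98%. Cluster 10 differed from the others in the make-up of its RNA. A single row took 37.0% of its UMIs, against 10.9% in cluster 11, the next highest value, and 3.47% in cluster 1. Over both libraries together cluster 15 was the deepest, with a median of 17702 UMIs per barcode and 4838 detected rows, although in library 1 the 12 barcodes of cluster 13 were deeper (33894 against 16335 UMIs). In library 2, where doublet removal did not work, cluster 15 had the highest median doublet score, 0.0685 against 0.0457 in cluster 1. Cluster 4 was the shallowest, with medians of 1144 UMIs in library 1 and 1268 in library 2, against 4923 and 7172 over all retained barcodes.

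**Figure D1:**
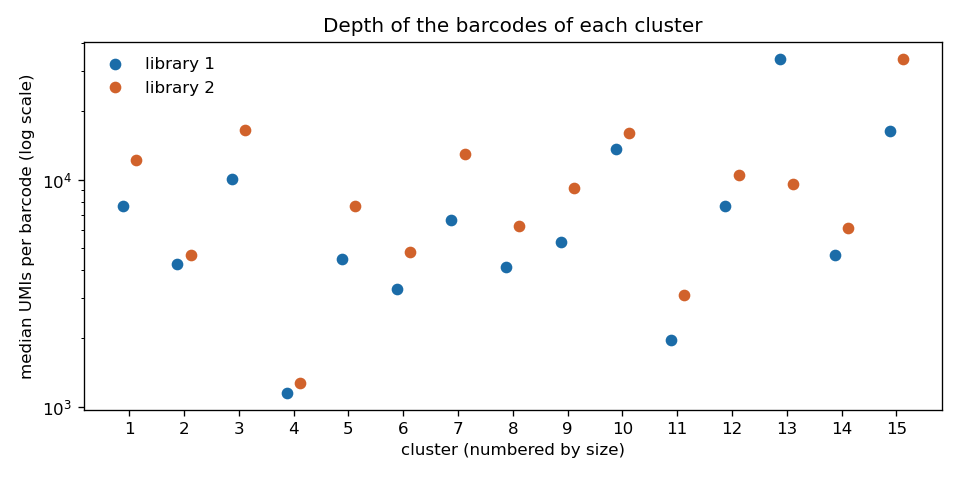
Median UMIs per barcode (log scale) for each of the 15 clusters, with 1 point per library. Cluster 4 lies lowest in both libraries (1144 and 1268 UMIs), and the 12 barcodes of cluster 13 in library 1 stand at 33894 UMIs against 9566 in library 2.

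The second question was whether the libraries held the same populations in the same proportions. Cluster 6 took 6.82% of library 1 (95% interval 6.33 to 7.34) and 6.89% of library 2 (6.22 to 7.62), and clusters 7, 8, 10, 12, 14 and 15 also had overlapping intervals. The intervals of the other 8 clusters did not overlap. Cluster 5 took 14.0% of library 1 (13.3 to 14.7) and 2.5% of library 2 (2.09 to 2.97), a 5.59-fold difference. This ratio depended on how the cells were divided: it was 3.13 with 4000 variable rows, 2.77 on 1 of 2 equal parts of the UMIs, 2.33 after centring, and 1.28 at resolution 0.25, where clusters 1 and 5 had the same match. Cluster 11 took 2.94% (2.61 to 3.29) and 1.13% (0.861 to 1.46), and cluster 3 took 13.3% (12.6 to 14.0) and 8.26% (7.52 to 9.05). In the other direction, cluster 13 took 0.123% of library 1 (0.0635 to 0.215) and 3.96% of library 2 (3.45 to 4.54). Scrublet called 262 doublets in library 1 and 1 in library 2, and how complete their removal was in library 1 was not measured. With predicted doublets kept the shares were 1.18% and 4.30%, so the ratio fell from 32.3 to 3.65. The shallow cluster 4 took 9.06% of library 1 (8.50 to 9.65) and 15.8% of library 2 (14.8 to 16.8). In all, 21.4% of barcodes would have to change cluster for the compositions to match, whereas random exchange of the library labels among barcodes gave at most 4.88% in 1000 draws. Barcodes are not replicates, so this range covers counting error only. The magnetic depletion can set such shares, and the libraries also differed in UMIs per barcode.

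**Figure D2:**
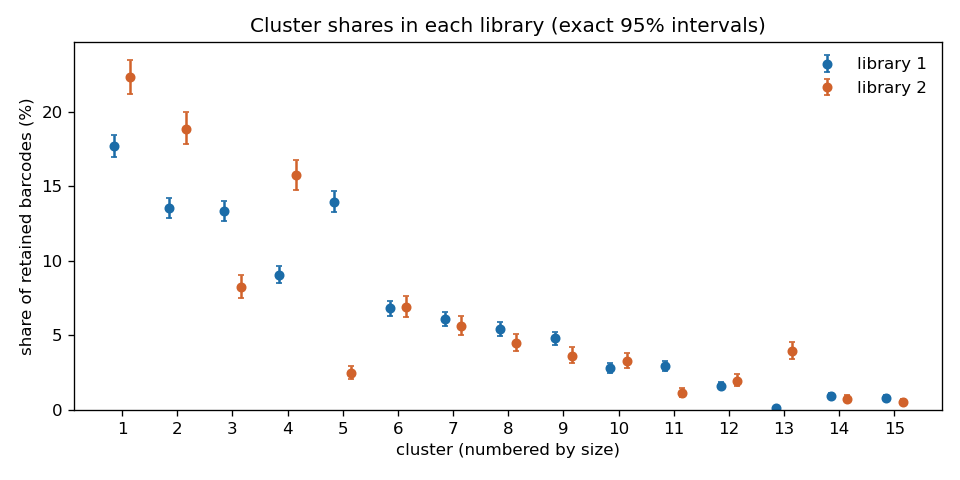
Share of retained barcodes (%) in each of the 15 clusters, with 1 point per library and bars for the exact 95% interval. Cluster 5 lies at 14.0% in library 1 and 2.5% in library 2, and cluster 13 at 0.123% and 3.96% (1.18% and 4.30% with predicted doublets kept), while cluster 6 lies at 6.82% and 6.89%.

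The profiles of the clusters were then compared between the libraries. For each of the 15 clusters, the summed profile in 1 library was closest to the same cluster in the other library, in both directions, with Spearman's rho from 0.892 (cluster 14) to 0.994 (cluster 1) across 16377 rows. Because the clusters were found on both libraries together, this closeness is built in to an unknown degree. Clusters 1 and 5 were each other's nearest different cluster (rho = 0.944), as were clusters 3 and 15 (0.939) and 8 and 9 (0.920). The nearest to cluster 7 was cluster 1 (0.941), and the nearest to cluster 2 was cluster 3 (0.928). Cluster 14 stood farthest apart, since its nearest neighbour, cluster 2, reached only 0.725. When each library was clustered alone, library 1 gave 15 clusters and library 2 gave 14, and 10 pairs were each other's best match (r = 0.590 to 0.941 across rows). The cluster of library 1 that corresponds to cluster 5 had a Jaccard index of 0.82 with it. In library 2 alone no such cluster formed, and the best match had an index of 0.0979. Clusters 11 (0.216) and 15 (0.0547) also had no close match in library 2 alone. The best match of cluster 2 there was a smaller cluster with 8.01% of barcodes (0.42), which was a reciprocal best match of its counterpart in library 1 alone (r = 0.905 across rows). Cluster 13 formed in library 2 alone (0.939) and not in library 1 alone (0.00538). Library 1 held only 12 of its retained barcodes, fewer than the 15 neighbours used, so clustering that library alone could hardly have shown otherwise.

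The third question was how many rows differed in expression between the populations. Of 15837 rows tested in 14 clusters, 13140 (83.0%) were higher or lower in at least 1 cluster than in the mean of the others (edgeR quasi-likelihood test, adjusted p under 0.05 and over 2-fold). Calls ranged from 3017 rows in cluster 8 to 6133 in cluster 6, of which 4178 were higher and 1955 lower. The order by size of change was another: the median absolute log2 fold change of the calls was largest in cluster 14 (2.59), against 2.20 in cluster 6. In 12 of the 14 clusters more rows were higher than lower. The exceptions were cluster 4 (2125 higher, 2527 lower), whose barcodes were the shallowest, and cluster 14 (1896 higher, 2068 lower). Cluster 13 was not tested because library 1 held only 12 of its barcodes. When clusters were found on 1 random part of the UMIs and tested on the other, 11165 rows of 13968 were called, 10682 of them among the 13140.

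Clusters differed in how many rows set them apart from every other cluster. In cluster 6, 610 rows had a CPM more than 4 times their highest CPM in any other cluster in both libraries. Rows with fewer than 20 UMIs in the cluster in either library were not counted. The corresponding numbers were 173 in cluster 14, 125 in cluster 12, 83 in cluster 11 and 38 in cluster 7. Cluster 5 had 9 such rows, clusters 1 and 3 had 1 each, and clusters 4 and 13 had 0. These counts were not tested, and they depend on how finely related cells were divided. They also depend on the total UMIs of a cluster, since 20 UMIs are a higher CPM where the total is low.

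**Figure D3:**
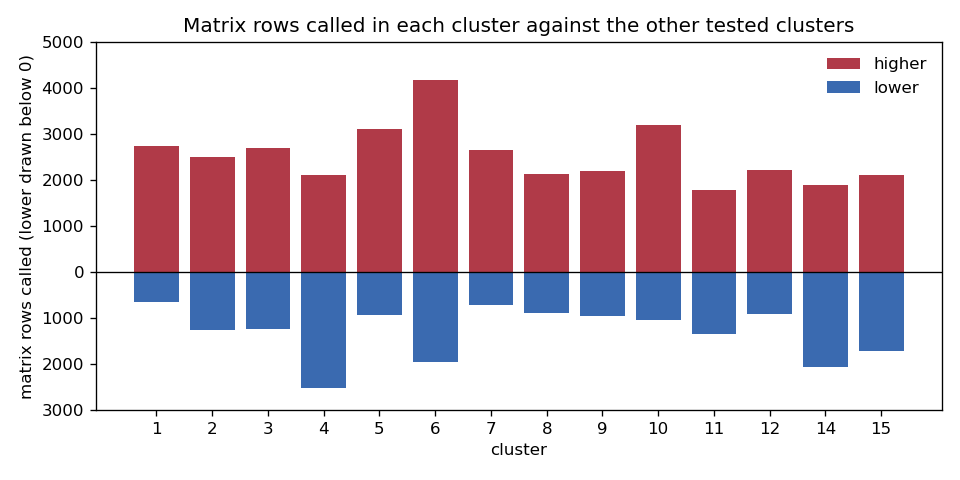
Number of matrix rows called higher (above 0) or lower (drawn below 0) in each of the 14 tested clusters against the mean of the others. Cluster 6 has the most calls (4178 higher, 1955 lower), and lower calls exceed higher calls only in clusters 4 and 14.

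In cluster 6, matrix row 4 had the largest rise, at 86.3 CPM in library 1 and 83.5 in library 2, from 258 and 210 UMIs. Over the other tested clusters together it stood at 0.524 and 1.12 CPM, which is 165-fold and 74.8-fold lower. The fitted log2 fold change against the mean of the other clusters was 10.04 (edgeR adjusted p = 2.02e-17). Its highest value in a single other cluster was 12.7 CPM. Matrix row 13555 stood at 101 and 93.5 CPM in cluster 6 against 1.40 and 1.82 CPM in the others, 71.8-fold and 51.4-fold higher (fitted log2 fold change 9.49, edgeR adjusted p = 3.66e-17), with 19.3 CPM as its highest value in a single other cluster. Matrix row 1550 had 0 UMIs in cluster 6 in both libraries and 10.0 and 9.57 CPM in the others together, although at least 1 other cluster was also at 0 CPM in a library. Against a limit of 3 counts per library, it was at least 9.96-fold lower in library 1 and at least 8.02-fold lower in library 2 (edgeR adjusted p = 0.000553). Matrix row 24551, also at 0 UMIs in cluster 6 and at 0 CPM in at least 1 other cluster in a library, was at least 4.16-fold and 4.65-fold lower (edgeR adjusted p = 4.45e-05). Both of these calls were lost under some alternatives, including the test on held-out UMIs, where the adjusted p was 1 for each at fitted log2 fold changes of -5.79 and -5.55 (-7.03 for both with all UMIs). With 4000 variable rows both calls were lost as well, at -2.17 and -2.37. With predicted doublets kept, row 1550 kept its call at -1.85 while row 24551 lost it at -4.02. Calls of both rows also changed at similar fitted values. Under the doublet score threshold of library 1 they were kept, at -6.67 (row 1550) and -6.88 (row 24551). With thinned clustering they were lost, at -6.65 and -6.69. Their adjusted p was thus unstable, and the held-out part also held fewer UMIs.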

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

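The values in this part were looked at only after the data were seen. In all, 12 barcodes outside all comparisons, 10 in library 1 and 2 in library 2, carried at least 500 UMIs on fewer than 100 detected rows. They stood out because 1 row held a median of 46.05% of their UMIs in library 1 and 42.9% in library 2, whereas the leading row of the retained barcodes held a median of 6.10% and 4.78%. The leading row was the same one in 10 of the 12 barcodes, and 3 different rows led among them. The 12 barcodes held 8918 and 2487 UMIs in the libraries. There were no control samples to compare with, and no explanation was tested.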

How the results depend on the processing

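The alternatives of thinned clustering, the library 1 doublet score in both libraries, equal cluster weights and omission of cluster 4 were chosen after the result was seen; the others were planned. The number of rows called in any cluster lay between 11165 (held-out UMIs) and 17518 (no filter on low counts, with 26548 rows tested) against 13140, within 1.5 times under all 13 alternatives. DESeq2, with no filter on low counts and 26548 rows tested, called 14120 rows, 12567 of them among the 13140, and the fit with no replicate block called 13168, of which 13113 were shared. Omitting the shallow cluster 4 gave 12402. Leaving out a library leaves no residual degrees of freedom, so it gave differences of log2(CPM + 1) with no test, which are not on the scale of the fitted fold changes: 6.10 and 6.17 for matrix row 4, 6.15 and 6.16 for row 13555, -2.62 and -2.55 for row 1550, and -2.35 and -2.03 for row 24551. Matrix rows 4 and 13555 kept their calls in all 13 tested alternatives, while rows 1550 and 24551 lost theirs in 4 and 6. The mean of the library medians moved from 6048 to 4425 UMIs and from 2503 to 1977 detected rows with a filter of 200 detected rows, under which Scrublet called 0 doublets in both libraries, and to 8469 UMIs and 3045 rows with a filter of 1000. The correlation between libraries, 0.9940, became 0.979 with thinned barcodes, 0.9958 with a minimum of 20 UMIs, 0.9922 with a pseudocount of 0.1 CPM and 0.9963 with equal cluster weights. The 58 rows over 2-fold apart became 128 with the smaller pseudocount, 84 of the 10949 rows left with thinned barcodes and 32 with equal cluster weights. Resolution 1.0 gave 24 clusters instead of 15; the other settings gave 12 to 17, and each library alone 14 and 15. The compositions differed by 21.4 percentage points, and by 16.3 at resolution 0.25, 19.0 after centring, 19.6 on 1 of 2 equal parts of the UMIs and 17.7 on barcodes thinned to 1000 UMIs. The causes of these shifts were not tested, apart from the changes in the barcodes or rows counted that each setting makes. The mean share of single clusters stayed within 1 SD in 85 of 135 values over clusters and settings. That SD was the spread between the 2 libraries, in percentage points 8.12 for cluster 5 and 0.053 for cluster 6. The count therefore depends on how far the libraries disagreed and does not measure stability across settings. Cluster 4 had the fewest UMIs per barcode, and clusters 13, 14 and 15 rest on the fewest barcodes. Comparisons of named cell classes and of the reporters were not run because they need gene names.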

Other observations

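The test of cluster 5 at equal UMI totals and the test of doublet calls for cluster 13 were chosen only after the result was seen; for the other tests, the bounds were set before the result, and the requirement that the 95% interval of a ratio also pass its bound was added afterwards, as was the comparison of cluster 4 with deeper clusters. The design names 1 group, so no biological explanation was tested for any of the 3 patterns below, and a difference between animals or dissections stays open as untested. The 95% intervals of the ratios below rest on barcodes, which are not replicates, and cover counting error only.

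Cluster 5 took 14.0% of library 1 and 2.5% of library 2. A first test of shallower barcodes in library 1, clustering barcodes thinned to 1000 UMIs, gave a ratio of 1.41, under the bound of 1.5 set for that explanation; it was set aside after its value was seen, because cluster 5 had merged with cluster 1 there (Jaccard index 0.383). The test that replaced it weighted both libraries to the same distribution over 10 bins of UMI total. The shares were then 12.9% and 2.79%, a ratio of 4.62 (95% interval 3.91 to 5.60). For the main clusters as they stand, this argues against the unequal UMI totals alone as the source of the ratio. The test took those clusters as given, so it cannot show whether depth shaped their division. The difference was not even over depth, from 9.37% against 0.411% in bin 2 to 3.21% against 2.95% in bin 9, counted from the shallowest. That the separation of clusters 1 and 5 itself needs more than 1000 UMIs per barcode stays open. So does an offset between the libraries in the same cells: after centring, the matched cluster took 18.2% and 7.81%, a ratio of 2.33 (2.11 to 2.59), between the bounds of 1.5 and 3, with a Jaccard index of 0.531.

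Cluster 13 took 3.96% of library 2 and 0.123% of library 1, a ratio of 32.3. Centring gave a ratio of 26.85 (95% interval 15.3 to 47.1, from 13 barcodes in library 1). Among the retained barcodes this argues against an offset shared by all cells of a library. Centring subtracts the mean over all barcodes of a library, so it cannot decide on an offset confined to the cells of this cluster. Predicted doublets were left out of that run, which by itself lowered the share of library 1. Whether an offset adds to the ratio left with doublets kept therefore stays open. That the cluster formed in library 2 alone does not bear on this, since an offset would allow it too. Doublet calls made part of the difference in shares. With doublets kept, 100 predicted doublets of library 1 and 0 of library 2 were in the matched cluster. The ratio fell from 32.3 to 3.65 (2.93 to 4.55). Whether the calls explain the difference as a whole stays open. The ratio was above the bound of 3 set against that explanation, but its interval includes the bound. The 100 predicted doublets of library 1 that joined the cluster had a median of 18269 UMIs and a doublet score of 0.295, against 10213 UMIs and 0.0295 for its 220 barcodes in library 2. The 12 barcodes of library 1 on which the share of 0.123% rests had a median score of 0.168, close under the threshold of 0.199 in that library. Whether the cluster holds doublets left in library 2 cannot be told apart from a population of its own. In library 2, 2 rows had a CPM over 4 times that in any other cluster and at least 20 UMIs. That number lay between the bounds of 0 and 10. Its median score of 0.0285 and 9566 UMIs in library 2 were both below those of cluster 1 (0.0457 and 12155). Its depth was, however, above the median of 7172 UMIs over all retained barcodes of library 2, so it decides nothing. With the doublet score threshold of library 1 its share of library 2 was 4.03%. That share rests on the same low scores and adds no separate evidence. The caller did not work in library 2, so these scores cannot decide the question.

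For the shallow cluster 4, droplets that hold free RNA stay open, because neither test separates them from ordinary cells. Cluster 4 had 0 rows with at least 20 UMIs and a CPM over 4 times that in any other cluster in both libraries. By the same rule, however, clusters 1 and 3, with medians of 9144 and 11127 UMIs, had 1 such row each and cluster 13 had 0. For free RNA that follows each library's other cells, 157 rows were taken as specific to cluster 5 by a looser rule. In library 1 they had at least 50 UMIs in cluster 5 and a CPM over 2 times that in any other cluster except cluster 4. Within cluster 4 these rows were higher in library 1 by 0.76 on the log2 scale, against 0.63 outside it, a quotient of 1.215. The value was higher still in cluster 13 (0.89, with 12 barcodes in library 1), lay between -0.01 (cluster 10) and 0.46 (cluster 7) in the other 13 clusters, and met the bound set for the explanation in 5 clusters besides cluster 4. Damaged cells of several types were not tested, since that needs gene names.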
